A study of Mus musculus with 24 samples.

How the data were processed

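The series holds 24 mouse samples: 21 bulk libraries made from small pools of sorted tendon cells and 3 single-cell libraries. Per the labels' protocols, the bulk libraries were built with a SMART-seq kit, which amplifies full-length cDNA, and the single-cell libraries with the 10x Genomics 3' kit. Cells were sorted by a red fluorescent reporter of Axin2, a Wnt target gene. Axin2+ cells carry the reporter and Axin2- cells do not. The single-cell counts list a Cre recombinase beside the reporter, so the reporter may mark earlier Axin2 activity. Axin2+ therefore need not mean Axin2 transcription at the time of the sort. Per the labels' protocols, the bulk gate left out cells with the endothelial marker CD31 or the leukocyte marker CD45, and the single-cell gate also left out cells with the red cell marker TER-119, which the bulk gate does not list. Bulk groups were uninjured tendon (homeostasis; 4 Axin2+ and 4 Axin2- libraries), injured tendon (4 Axin2+ and 2 Axin2-) and the uninjured contralateral tendon of injured animals (4 Axin2+ and 3 Axin2-). The single-cell libraries are 1 of homeostatic tendon, 1 of tendon 10 days after injury (10 dpi) and 1 of sorted Axin2 reporter-positive cells at 10 dpi. Groups and replicate names, which are plate positions, come from the sample titles. Nothing in the labels ties wells to animals, so p-values measure the spread between these libraries, which may be partly technical.

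Per the submitters' processing notes, the tools were Trimmomatic, Salmon 0.13.1 and DESeq2 1.24.0 for bulk libraries and Cell Ranger, Seurat and Scanpy for single cells, on mouse build mm10. The 2 bulk tables that the authors deposited, 1 for homeostasis and 1 for the injury experiment, hold a signal of scaled reads: read counts per gene divided by a factor per library. Although 1 table is named for TPM, its library totals ranged from 5570725 to 73762248, and 100% of values in both were whole multiples of the value of 1 read (relative tolerance 1e-06). That value was 0.355 to 6.33 in the homeostasis table and 0.271 to 4.22 in the injury table. The tables were scaled separately, so every test stayed within 1 table. The planned minimum in TPM was replaced by the same minimum in scaled reads as in the other table, and the planned comparison with a TPM table of the homeostasis libraries was not run because that table holds the injury libraries. The single-cell files that the authors deposited hold raw UMI counts per gene and barcode.

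The bulk tables list 53468 gene identifiers. Of these, 53363 were found in GENCODE vM21, which supplied coordinates on GRCm38/mm10 (1-based). Symbols came from the deposited injury table, and 192 identifiers shared a symbol with another. No replicate pair agreed within sampling noise (smallest chi-square per degree of freedom 15.9, between homeostasis replicates A5 and A7). The test was limma 3.58.1 with a mean-variance trend (R 4.3.3) on log2(scaled reads + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes on this scale understate the change of low genes. Genes needed 10 scaled reads in at least 4 of 8 homeostasis libraries or 3 of 13 injury libraries. The 4 injury groups were fitted together, and the difference between the injury responses of Axin2+ and Axin2- cells was the interaction term. Where every library of a group was at 0, the fold is given as a lower bound against 3 reads over the whole group. These bounds and all intervals cover counting error only.

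Gene lists fixed before the data were examined were tested with camera (preset correlation 0.01), then with an estimated correlation, and with fry, which asks whether a list's genes move one way on balance. A list needed 3 tested members. Scx, Tnmd, Fmod, Thbs4, Comp, Dcn, Col1a1 and Col1a2 are in both the tendon identity and the tendon fibroblast marker list. Calls of these lists are therefore not separate results. The 28 lists were tendon identity, Wnt receptors and secretion, Wnt ligands, Wnt feedback and target genes, secreted Wnt inhibitors, cell cycle, sheath and progenitor-associated fibroblast genes, repair matrix and myofibroblast genes, cartilage and bone genes, TGF-beta and BMP pathway, Hedgehog pathway, matrix proteases and inhibitors, chemokines and cytokines, immediate-early and dissociation-response genes, and markers of macrophages, neutrophils, T and NK cells, B cells, endothelium, pericytes and smooth muscle, Schwann cells, skeletal muscle, satellite cells, erythroid cells, adipocytes, keratinocytes, tendon fibroblasts and chondrocytes. In each comparison the text names Axin2, Scx, Tnmd, Mkx and Mki67, up to 8 genes per direction with the largest fold among those that passed the test and whose groups did not overlap, and up to 4 members per list by smallest p; where fewer than 3 passed in a direction, the 5 with the smallest p are named as not passing. Some genes that this rule names are not reported here. Other list members named for lists in which no member passed were chosen after their values were seen.

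The limma step was tested on simulated data drawn from the real means and depths, with 200 changed genes. Unchanged genes made up most limma calls for the contralateral (1513 calls in all), injured (1889), Axin2- injury (867) and interaction (71) designs. With so few changed genes, these shares cannot be carried over to the real counts. For homeostasis (14513 genes) it recovered 33.3% of genes changed 4-fold, 96.6% changed 16-fold and 100% changed 64-fold, and called 5 unchanged genes. For the contralateral comparison (20524 genes) it recovered 13.6%, 40.0% and 61.9% and called 1439 unchanged genes. For the injured comparison (20521 genes) the shares were 23.0%, 32.8% and 65.6% with 1813 unchanged genes called. For Axin2+ injury (20516 genes) the 4-group fit recovered 0%, 0% and 10.2% and called 0 unchanged genes, and a fit to the 2 groups alone (18084 genes) recovered 13.6%, 75.9% and 92.9% and called 13. For Axin2- injury (20554 genes) the shares were 9.09%, 10.9% and 34.8% with 831 unchanged genes called, and for the interaction (20520 genes) 0%, 3.08% and 12.9% with 61. Because whole reads could be recovered, edgeR 4.0.16 (quasi-likelihood test) was run on them as an alternative chosen after seeing the data; on the simulated libraries it called 8, 143 and 0 unchanged genes for homeostasis, contralateral and injured tendon and recovered 100%, 52.4% and 1.56% of genes changed 64-fold.

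Single cells were analysed with scanpy 1.11.5, anndata 0.12.19 and igraph 0.11.9 (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1; figures with matplotlib 3.10.9). Each file set lists 6794880 barcodes. Cells needed 1000 UMIs, 500 genes and at most 10% mitochondrial UMIs. Scrublet marked 1, 1 and 2 cells as doublets in the homeostasis, 10 dpi and sorted libraries, and these were removed; so few marks leave doublets possible. Clustering used 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5. Clusters took a name from marker lists fixed before the data were examined, and otherwise stayed unnamed. A further rule, outside those lists, withheld an erythroid name where Cma1, Mcpt4, Tpsb2 or Cpa3 was among the 10 leading genes. It kept cluster 2 unnamed. Collagen-rich clusters below are the unnamed or tendon fibroblast-like ones above 1000 Col1a1 counts per 1e6 UMIs. They include cluster 2, led by globin genes, Cma1 and Cpa3 (39 homeostasis, 7 10 dpi and 9 sorted cells). Pericyte-like cells are left out, whatever their Col1a1. With 1 library per group no test was possible, and no p-value is given. UMIs were summed per class, and ratios of counts per 1e6 UMIs (CPM) carry exact 95% intervals. A list's median log2 ratio was placed among 10000 random lists matched on expression in 20 bins. Random lists draw genes independently, so a percentile does not allow for genes that rise together in a few cells. Summed counts under 3 UMIs were set to 3, and members needed 20 UMIs in the 2 libraries together. The percentile was tried on simulated summed counts with counting error only, without variation between cells. For 10 dpi over homeostasis (6792 genes), a list raised 4-fold had a median log2 ratio of 2.15 (percentile 100). An unchanged list had -0.29 (percentile 8.15). For the sort over 10 dpi (7189 genes), the raised list had 1.92 (percentile 100) and the unchanged list -0.05 (percentile 66.15). Raised genes took share from the unchanged list, so its values are no exact null. Genes named for single cells were the 8 highest and 8 lowest CPM ratios among genes at 100 CPM or more, and up to 4 members per pathway list by size of ratio.

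Alternatives planned before the data were examined were other pseudocounts, filters and scalings, array weights, fits to fewer groups, each library left out in turn, and other cell filters and resolutions. Those chosen after seeing the data were edgeR, a term for the plate section (A1 to A4 or A5 to A8; B10 to C4 or C5 to C11), scaling without globin genes, each homeostasis plate section alone, a minimum of 1 scaled read, neighbouring wells of the injury experiment as a block, thinning of the Axin2+ libraries to the median non-globin depth of the Axin2- libraries, and single-cell sets without T and NK cells, of all collagen-rich clusters or of all cells.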

Results

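Transcription was compared between Axin2+ and Axin2- cells of mouse tendon in 21 bulk libraries, with and without injury, and in 3 single-cell libraries. Axin2 is a Wnt target gene and a negative regulator of Wnt/beta-catenin signalling. Bulk depth, in reads assigned to genes, was 2816340 to 15796554 for homeostasis Axin2+ libraries (n = 4) and 2456145 to 10047330 for homeostasis Axin2- (n = 4). In the injury experiment it was 6576615 to 21775181 for contralateral Axin2+ (n = 4), 14813397 to 17820973 for contralateral Axin2- (n = 3), 5109256 to 19205598 for injured Axin2+ (n = 4) and 3599728 to 17485471 for injured Axin2- (n = 2). Genes with at least 10 reads ranged from 18185 to 24283 in contralateral Axin2+ libraries and from 6057 to 11324 in contralateral Axin2- libraries. Injured Axin2+ libraries held 13926 to 24197 such genes and injured Axin2- libraries 6585 to 8231. Homeostasis libraries held 11882 to 21403 (Axin2+) and 7354 to 22132 (Axin2-). The alpha and beta globin genes took 49.7 to 62.7% of contralateral Axin2- reads, 54.7 to 59.4% of injured Axin2- reads and 0.0905 to 2.90% of homeostasis Axin2- reads. In every Axin2+ library they took at most 0.00519%. Mitochondrial genes took 4.58 to 9.83% of contralateral Axin2- reads and 1.97 to 2.47% of contralateral Axin2+ reads. Injured Axin2- libraries, at 3.11 and 6.64%, overlapped with injured Axin2+ libraries, at 1.84 to 3.22%. Values below are scaled reads, as mean ± SD over libraries.

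In uninjured tendon, the transcripts of haemoglobin, the oxygen carrier of red blood cells, were lower in Axin2+ than in Axin2- libraries. Hba-a2 (chromosome 11, 32296489 to 32297298) stood at 42.4 ± 82.6 in Axin2+ and 91614 ± 92696 in Axin2- libraries (n = 4 each), a log2 fold change of -12.70 (SE 1.61, limma adjusted p = 0.0202). Hbb-bs (chromosome 7, 103826534 to 103828096), Hbb-bt and Hba-a1 had log2 fold changes of -12.40, -10.92 and -10.88 (limma adjusted p = 0.0202, 0.0340 and 0.0133). Gbp5, an interferon-induced guanylate-binding protein (chromosome 3, 142493978 to 142522344), was higher in Axin2+ libraries, at 392 ± 142 against 32.1 ± 11.9 (log2 fold change 3.57, SE 0.39, limma adjusted p = 0.0124). Fam102a (chromosome 2, 32535332 to 32569756) was higher at 775 ± 205 against 136 ± 9.48 (log2 fold change 2.46, SE 0.28, limma adjusted p = 0.0124). The remaining gene higher in Axin2+ was the predicted gene Gm28437 (log2 fold change 7.53, limma adjusted p = 0.00762). Axin2 itself (chromosome 11, 108920349 to 108950783) stood at 21.2 ± 21.9 in Axin2+ and 15.4 ± 7.45 in Axin2- libraries, with a log2 fold change, taken between means of logs and here of the other sign than the means, of -0.40 (SE 0.96, limma adjusted p = 0.974). Scx, a transcription factor of the tendon lineage, stood at 1045 ± 1352 and 1995 ± 3114, and Tnmd, a tendon membrane glycoprotein, at 5954 ± 3097 and 10650.4 ± 7548 (limma adjusted p = 0.994 and 0.957). Mkx, a homeobox factor of tendon, stood at 1602 ± 429 and 1115 ± 468, and the proliferation marker Mki67, too low to test, at 17.8 ± 24.8 and 19.99 ± 19.9. Of 15267 genes tested, limma called 7, with 3 higher and 4 lower in Axin2+ libraries, and 577 had an unadjusted p under 0.05. The groups did not overlap for 406 genes (2.66%, against 2.86% by chance). edgeR called 4 genes (75.0% higher, 3 shared with limma), and scaling without globins left 3 (66.7% higher). With pseudocount 0.1 limma called 2 genes (100% higher), so the 4 globin calls ended. limma called 0 genes without A3 (509 at unadjusted p under 0.05), A5 (352) or A7 (510), 2 without A2 or A4 (100% higher), 4 without A8 (75.0% higher) and 17 without A6; within wells A1 to A4 it called 34, and within A5 to A8 0 (462 at unadjusted p under 0.05).

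Among the lists in uninjured tendon, genes of chemokine signalling, stress response and vessels stood lower in Axin2+ libraries relative to all genes, whose median log2 fold change was 0.12. Of 15 chemokine and cytokine genes, 14 were lower (median -1.55, camera adjusted p = 2.87e-08; adjusted p = 0.528 with an estimated correlation). Adjusted over the list alone, Cxcl10 and Ccl11, attractants of T cells and eosinophils, were lower, at log2 fold changes of -3.03 and -2.88, and 0 members passed over all genes. Of 16 immediate-early genes, 15 were lower (median -0.78, camera adjusted p = 8.16e-06; adjusted p = 0.589 with an estimated correlation), with 0 passing over all genes and 0 adjusted over the list alone. All 8 endothelial markers were lower (median -1.27, camera adjusted p = 2.76e-05; adjusted p = 0.1301 with an estimated correlation), with 0 passing by either adjustment. Pericyte and smooth muscle markers were lower in 7 of 9 (median -1.19, camera adjusted p = 3.23e-05), and Rgs5, a pericyte signalling regulator, passed when adjusted over the list alone (log2 fold change -1.74). All 5 erythroid markers were lower (median -10.92, camera adjusted p = 1.11e-23), 4 over all genes and 5 adjusted over the list alone. The pericyte and erythroid lists kept their calls with an estimated correlation (adjusted p = 0.0407 for both).

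Sheath and progenitor-associated genes were lower in 8 of 13 (median -0.28, camera adjusted p = 0.00137; adjusted p = 0.589 with an estimated correlation). Tppp3, a tendon sheath marker, passed when adjusted over the list alone (log2 fold change -2.04), and the list was not called without A8 (camera adjusted p = 0.291). Repair matrix genes were lower in 12 of 18 (median -0.59) and tendon fibroblast markers in 10 of 11 (median -0.65), both with camera adjusted p = 0.0121 and adjusted p = 0.615 with an estimated correlation. No member of either passed over all genes or adjusted over the list alone. The repair matrix call ended without A1 (0.0696), A4 (0.127) or A8 (0.394) and with quantile normalization (0.872), and the tendon fibroblast call without A3 (0.0738), A4 (0.0941) or A8 (0.385) and with quantile normalization (0.855). Scaling to equal totals or without globins raised the median of all genes by 0.49 or 0.47, which turned the sheath list's median to 0.23 or 0.20 while its call, relative to all genes, stayed lower.

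The lists of Wnt signalling and tendon identity were not called in uninjured tendon. Wnt receptors and secretion genes were higher in 11 of 16 (median 0.33, camera adjusted p = 0.166), Wnt ligands in 3 of 6 (median -0.24, 0.306) and Wnt feedback genes in 7 of 12 (median 0.13, 0.882). Secreted Wnt inhibitors were higher in 5 of 7 (median 0.04, mean -0.20, camera adjusted p = 0.882), and Sfrp1 was lower when adjusted over the list alone (log2 fold change -2.96). Tendon identity genes were lower in 10 of 12 (median -0.58, camera adjusted p = 0.123), and matrix proteases in 10 of 14 (median -0.34, 0.0586). Cell cycle (11 of 17 higher), cartilage and bone (5 of 9), TGF-beta and BMP (8 of 19) and Hedgehog genes (4 of 6) each had a camera adjusted p of 0.882; the cell cycle list had a median of 0.13 with a test direction of lower, and the TGF-beta list a median of -0.02 and a mean of 0.07. Markers of macrophages (1 of 5 higher), Schwann cells (2 of 5), skeletal muscle (6 of 6, median 1.38) and satellite cells (1 of 4) each had a camera adjusted p of 0.248; T and NK cell markers (2 of 4) had 0.611 and chondrocyte markers (5 of 6) 0.415. No member of these lists passed over all genes, and none but Sfrp1 adjusted over the list alone. Neutrophil, adipocyte, keratinocyte and B cell markers had too few tested members.

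In contralateral tendon of injured animals, tendon matrix and tendon identity genes were higher in Axin2+ than in Axin2- libraries, and red blood cell genes were lower. Tnmd (chromosome X, 133850980 to 133865577) stood at 8064 ± 3526 in Axin2+ (n = 4) and 0.894 ± 1.55 in Axin2- libraries (n = 3), a log2 fold change of 12.25 (SE 0.91, limma adjusted p = 2.78e-06). Comp, a cartilage and tendon matrix protein (chromosome 8, 70373558 to 70382066), stood at 25515 ± 8933 against 21.7 ± 26.3, and Mmp2, a gelatinase (chromosome 8, 92827291 to 92853420), at 14618 ± 3726 against 7.63 ± 6.67. Their log2 fold changes were 11.35 and 11.38. Col1a1, a chain of type I collagen (chromosome 11, 94936224 to 94953042), stood at 196890.0 ± 110498 against 1799 ± 789.9 (log2 fold change 6.73, SE 0.81, limma adjusted p = 3.37e-05). Gas6, a ligand of TAM receptors (chromosome 8, 13465374 to 13494490), was at least 1342-fold higher, Arf1 at least 1315-fold and Plpp1 at least 1125-fold, each at 0 in Axin2- libraries. Htra1, a secreted serine protease, and Il11ra1, an interleukin-11 receptor, were higher by 11.61 and 11.31 on the log2 scale. Hbb-bt (chromosome 7, 103812524 to 103813996) stood at 1.17 ± 0.775 in Axin2+ and 2408440 ± 1916680 in Axin2- libraries (log2 fold change -19.86, SE 1.06, limma adjusted p = 2.58e-07). Log2 fold changes were -19.39 for Hbb-bs, -19.26 for Hba-a1, -18.45 for Hba-a2, -15.81 for Alas2, the haem synthesis enzyme of red cells (chromosome X, 150547375 to 150570638), -14.35 for Apol11b and -12.74 for Rsad2. Axin2 stood at 12.1 ± 4.57 in Axin2+ and 95.03 ± 131 in Axin2- libraries (log2 fold change -0.80, SE 1.61, limma adjusted p = 0.728). Scx stood at 5708 ± 9288 and 283 ± 465 (log2 fold change 4.56, SE 2.52, limma adjusted p = 0.172), and Mki67 at 12.7 ± 11.5 and 9.08 ± 13.5 (limma adjusted p = 0.717).

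Of 21336 genes tested, limma called 7760 in contralateral tendon, 6580 higher and 1180 lower in Axin2+ libraries (84.8% higher), and 6961 of these had groups that did not overlap. Over all genes, groups did not overlap for 8712 (40.8%, against 5.71% by chance). Array weights gave 4946 calls, and edgeR 6782 with 64.5% higher (5440 shared with limma). The median log2 fold change of all genes was 1.81; quantile normalization moved it to -0.20 and the share of higher calls to 49.4%, and scaling without globins raised it by 0.79 and the share to 94.8%. Of the 85 called genes named by the fixed rule, 59 kept their call under every alternative; the genes named for this comparison are among them unless a value says otherwise. On simulated libraries of this design limma called 1439 unchanged genes and edgeR 143.

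Tendon identity genes were higher in all 12 tested members in contralateral tendon, 11 of them past the test over all genes and 11 adjusted over the list alone (median 8.23, camera adjusted p = 2.59e-06). Kera and Chad, leucine-rich matrix proteins, had log2 fold changes of 10.12 and 9.90, Mkx 8.66 (1538 ± 101 against 17.8 ± 30.9) and Col1a2 6.48. Tendon fibroblast markers were higher in 11 of 11, with 8 called and 8 adjusted over the list alone (median 6.73, camera adjusted p = 0.000952). Erythroid markers were lower in 6 of 6, with 6 called and 6 adjusted over the list alone (median -18.86, camera adjusted p = 1.21e-16). These lists kept their calls with an estimated correlation (adjusted p = 0.00985, 0.0468 and 0.0138). Repair matrix genes were higher in 17 of 18 (median 6.51, camera adjusted p = 0.000343; adjusted p = 0.277 with an estimated correlation), 15 of them called and 16 adjusted over the list alone. Among these, Lox, a collagen crosslinking enzyme, was higher by 8.46 on the log2 scale, Col12a1 by 8.19, Postn, the matrix protein periostin, by 7.58, and Acta2, smooth muscle actin, at least 685-fold.

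TGF-beta and BMP pathway genes were higher in 20 of 21 in contralateral tendon (median 4.09, camera adjusted p = 0.00608; adjusted p = 0.277 with an estimated correlation), with 12 called and 16 adjusted over the list alone. Tgfb3 was at least 766-fold higher, the BMP target Id1 at least 118-fold, Id3 by 9.92 and Bmp4 by 7.11 on the log2 scale. Matrix proteases and inhibitors were higher in 15 of 16 (median 4.91, camera adjusted p = 0.00935; adjusted p = 0.277 with an estimated correlation), with 10 called and 11 adjusted over the list alone. Mmp23 was at least 139-fold higher, and Timp1, a protease inhibitor, and Adamts4 had log2 fold changes of 8.33 and 6.81. Immediate-early genes were higher in 16 of 16 (median 7.48, camera adjusted p = 0.00492; adjusted p = 0.612 with an estimated correlation), with 13 called and 13 adjusted over the list alone; Ier3, Zfp36 and Socs3 had log2 fold changes of 9.80, 7.82 and 8.09. Pericyte and smooth muscle markers were higher in 10 of 10 (median 4.29, camera adjusted p = 0.0118; adjusted p = 0.313 with an estimated correlation), with 8 called and 9 adjusted over the list alone; Rgs5, Kcnj8 and Notch3 had log2 fold changes of 9.58, 6.35 and 5.97. Without contralateral Axin2- replicate C4, the protease (0.0840), immediate-early (0.105) and pericyte (0.0527) lists were not called.

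Wnt pathway lists were not called against all genes in contralateral tendon, although single members were higher in Axin2+ libraries. Among Wnt receptors and secretion genes, 15 of 16 were higher, 8 called and 9 adjusted over the list alone (median 3.35, camera adjusted p = 0.0569). Porcn, which acylates Wnt proteins, was at least 45.1-fold higher, and Wls, which carries them to the surface, and the receptor Fzd7 had log2 fold changes of 6.07 and 5.49. Wnt ligands were higher in 12 of 12, with 2 called and 2 adjusted over the list alone (median 1.96, camera adjusted p = 0.670); Wnt9a had a log2 fold change of 5.51. Feedback and target genes were higher in 13 of 15 (median 2.38, camera adjusted p = 0.550), with 6 higher and 1 lower called, and 7 higher and 1 lower adjusted over the list alone. Bambi and the Wnt feedback antagonist Znrf3 were higher by 6.34 and 5.28 on the log2 scale. The R-spondin receptor Lgr6 had -4.08, a call that ended with array weights (limma adjusted p = 0.0844). Secreted Wnt inhibitors were higher in 7 of 8 (median 6.85, camera adjusted p = 0.0767), with 5 called and 5 adjusted over the list alone: Wif1 at least 854-fold, and Dkk3, Sfrp2 and Dkk2 with log2 fold changes of 8.45, 8.06 and 7.61.

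The other lists were not called in contralateral tendon, where a median near 1.81 is that of all genes. Cell cycle genes were higher in 20 of 24 (median 2.80, or 2.73 with members at 0 at their bounds; camera adjusted p = 0.633), with 6 called and 6 adjusted over the list alone, among them the replication factors Pcna (log2 fold change 7.71) and Mcm4 (at least 60.6-fold). Sheath genes were higher in 13 of 13 (7 called, 8 adjusted over the list alone; median 4.08, camera adjusted p = 0.189), chemokines in 15 of 16 (9 and 9; 4.26, 0.0855), cartilage and bone genes in 9 of 13 (6 and 7; 3.08, 0.468) and Hedgehog genes in 7 of 7 (0 and 0; 1.81, 0.933). Cxcl1, a neutrophil attractant, and Sox9, the cartilage master regulator, had log2 fold changes of 8.60 and 7.99. Macrophage markers were higher in 7 of 9 (1 called; median 2.34, or 1.98 with bounds; 0.847), with Cd68 at least 33.5-fold. T and NK cell markers were higher in 4 of 6 (median 0.34, 0.370), B cell in 4 of 7 (0.20, 0.468), endothelial in 8 of 11 (1.05, 0.6002), Schwann cell in 7 of 8 (1.34, 0.962), skeletal muscle in 3 of 8 (-0.41, 0.205), satellite cell in 6 of 6 (3.05, or 2.80 with bounds; 0.468) and chondrocyte markers in 7 of 8 (5.09, or 4.85 with bounds; 0.135). The test, which is relative to all genes, pointed lower for T and NK, B, endothelial and Schwann cell markers. Neutrophil, adipocyte and keratinocyte markers had too few tested members in the injury experiment.

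**Figure D1:**
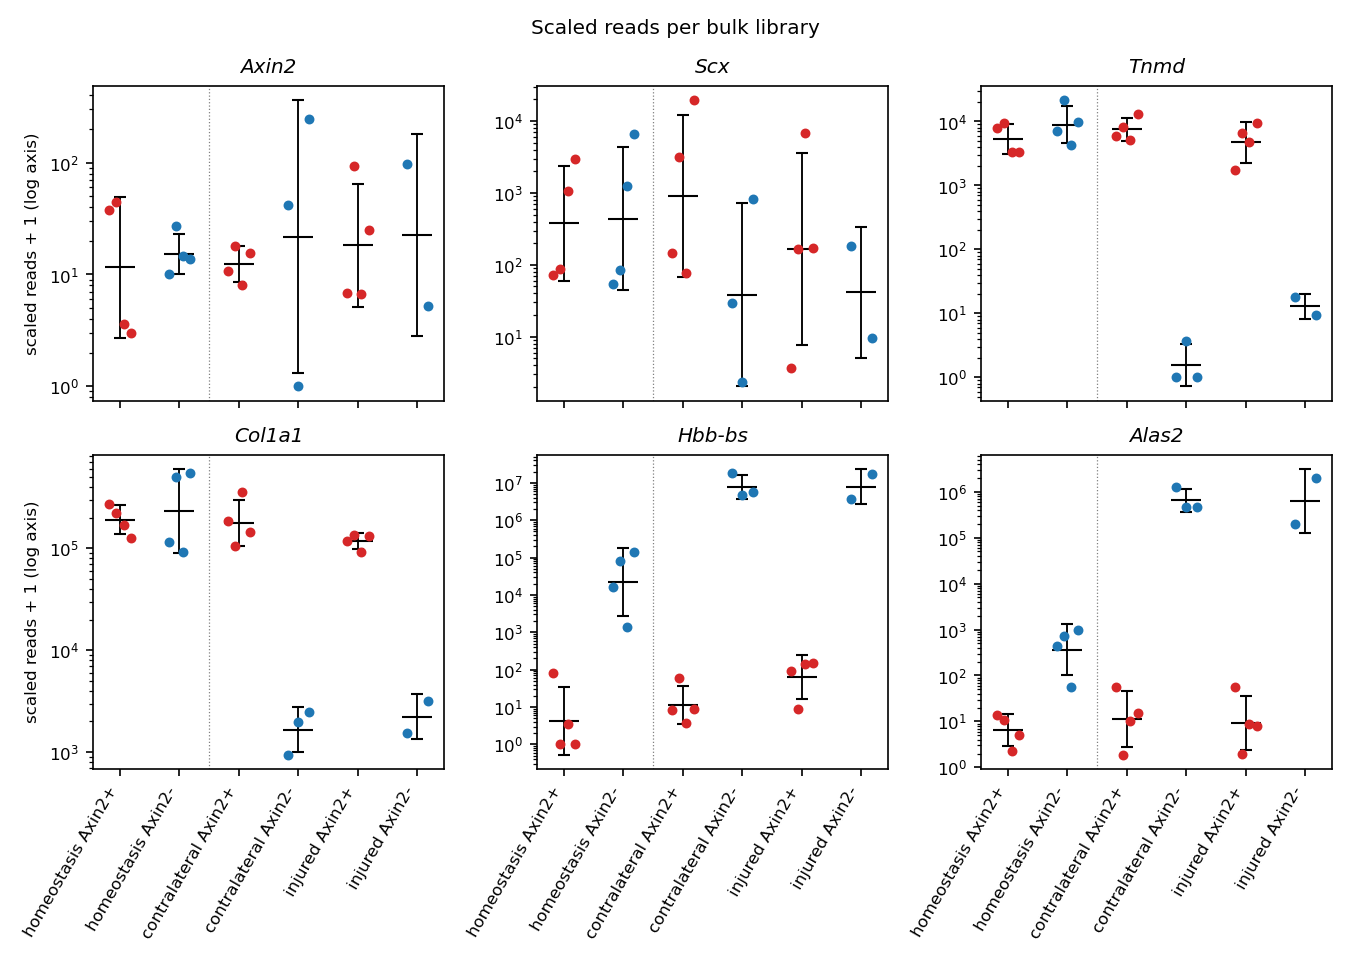
Scaled reads + 1 on a log axis for Axin2, Scx, Tnmd, Col1a1, Hbb-bs and Alas2 in each bulk library, with Axin2+ in red and Axin2- in blue; black bars are the geometric mean and the SD of log10 values, and the dotted line parts the homeostasis table from the injury table, which were scaled separately. Tnmd averaged 8064 in contralateral Axin2+ and 0.894 in contralateral Axin2- libraries, while Axin2 averaged 12.1 and 95.03.

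In injured tendon, tendon matrix genes were again higher in Axin2+ (n = 4) than in Axin2- libraries (n = 2), and red blood cell genes lower. Tnmd stood at 5613 ± 3217 against 12.7 ± 5.97 (log2 fold change 8.51, SE 1.03, limma adjusted p = 5.96e-05). Kera was at least 754-fold higher, Itgbl1, an integrin beta-like protein, at least 775-fold and Dpt, the matrix protein dermatopontin, at least 682-fold, each at 0 in Axin2- libraries. Tuba1a was at least 1174-fold higher, Itm2a at least 1129-fold, S100a6 at least 877-fold, Ly6a (Sca-1) at least 775-fold and Cnn3 at least 729.7-fold, and the AP-1 factor Junb stood at 12862 ± 8675 against 2.11 ± 2.98. Chad, Thbs4, Mkx and Fmod had log2 fold changes of 10.26, 9.51, 7.70 and 7.11. Col1a1 stood at 118539 ± 19815 against 2373 ± 1166 (log2 fold change 5.72, limma adjusted p = 0.000484; 0.086 without a filter). Among genes lower in Axin2+ libraries, log2 fold changes were -17.60 for Hba-a1 (SE 1.35), -17.27 for Hbb-bt, -16.93 for Hbb-bs, -16.13 for Hba-a2, -16.05 for Alas2 and -12.52 for Trim10. Axin2 stood at 32.2 ± 41.4 and 50.6 ± 65.7 (log2 fold change -0.32, SE 1.82, limma adjusted p = 0.916), Scx at 1809 ± 3391 and 94.96 ± 122 (1.99, SE 2.86, 0.643), and Mki67 had a log2 fold change of 0.85 (0.757). limma called 5852 genes, 5142 higher and 710 lower (87.9% higher), and 5742 had groups that did not overlap. Over all genes, groups did not overlap for 10044 (47.1%, against 13.3% by chance). Array weights gave 2736 calls and edgeR 3264 (76.6% higher). The median of all genes was 1.70; quantile normalization moved it to -0.21 and the share of higher calls to 50.8%, and scaling without globins raised it by 0.75 and the share to 95.8%. Of the 84 called genes named by the rule, 57 kept their call under every alternative. On simulated libraries 1813 of limma's 1889 calls were unchanged genes, a share that cannot be carried over to the real calls either. There edgeR called 0 unchanged genes, with 1 call in all and 1.56% of genes changed 64-fold recovered.

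Tendon identity genes were higher in 12 of 12 in injured tendon, 11 called and 11 adjusted over the list alone (median 8.11, camera adjusted p = 5.55e-06). Tendon fibroblast markers were higher in 11 of 11, 8 called and 10 adjusted over the list alone (median 6.85, camera adjusted p = 0.000519), and erythroid markers lower in 6 of 6, all 6 called by either adjustment (median -16.53, camera adjusted p = 3.85e-17). These lists kept their calls with an estimated correlation (adjusted p = 0.0120, 0.0375 and 0.0125). Repair matrix genes were higher in 17 of 18 (median 6.28, or 5.97 with members at 0 at their bounds; camera adjusted p = 0.000387), 13 called and 13 adjusted over the list alone. Tnc, tenascin C, was at least 334-fold higher, and Col5a2, Sparc and Lox had log2 fold changes of 10.71, 9.59 and 8.44. Chemokines were higher in 15 of 16 (median 6.78, or 5.68 with bounds; camera adjusted p = 0.00108), 13 called and 13 adjusted over the list alone, with the alarmin Il33 at least 60.1-fold and Cxcl1 and Ccl7 at log2 fold changes of 9.65 and 9.18. Immediate-early genes were higher in 14 of 16 (median 8.39, camera adjusted p = 0.00158), 13 called and 14 adjusted over the list alone, with Ier3, Atf3 and Btg2 at 9.56, 9.41 and 9.13. With an estimated correlation these calls were lost (adjusted p = 0.215 for repair matrix, 0.369 for chemokines and 0.433 for immediate-early genes).

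Proteases were higher in 15 of 16 in injured tendon (median 6.17, or 5.02 with bounds; camera adjusted p = 0.00551), 9 called and 11 adjusted over the list alone, with Mmp14, Mmp23, Adamts1 and Mmp2 at log2 fold changes of 9.79, 8.47, 6.91 and 6.39. Sheath genes were higher in 13 of 13 (median 4.65, camera adjusted p = 0.00891), 7 called and 8 adjusted over the list alone, with Cd34, the hyaluronan synthase Has1 and Sema3c at 10.60, 10.30 and 7.25. Pericyte markers were higher in 10 of 10 (median 5.74, or 4.08 with bounds; camera adjusted p = 0.00891), 7 called and 7 adjusted over the list alone, with Rgs5 and Cspg4 at 6.48 and 5.82. Secreted Wnt inhibitors were higher in 7 of 8 (median 6.68, or 6.14 with bounds; camera adjusted p = 0.0421), 6 called and 6 adjusted over the list alone, with Wif1 and Dkk3 at 8.60 and 7.48. These 4 calls were lost with an estimated correlation (adjusted p = 0.215 for proteases, 0.433 for sheath, 0.262 for pericyte and 0.215 for Wnt inhibitor genes). Without C6 the protease (0.0827), pericyte (0.191) and Wnt inhibitor (0.111) lists were not called, and without B11 the sheath (0.0829) and Wnt inhibitor (0.0556) lists. The Wnt inhibitor list was also not called without C1 (0.0802), C4 (0.0773) or C8 (0.0754) or when scaled without globins (0.0636).

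The remaining lists were not called in injured tendon. Wnt receptors and secretion genes were higher in 14 of 16 (6 called, 6 adjusted over the list alone; median 3.14, or 2.53 with bounds; camera adjusted p = 0.170), with Porcn at least 37.4-fold and Fzd7 and Wls at log2 fold changes of 5.49 and 5.11. Wnt ligands were higher in 12 of 12 (4 and 5; 3.41, or 2.22 with bounds; 0.0670), with Wnt9a at least 25.6-fold, and feedback genes in 12 of 15 (3 and 3; 1.45; 0.861), with Bambi at 6.44. TGF-beta and BMP genes were higher in 19 of 21 (median 4.04, 0.0670), 10 higher and 1 lower called and 11 higher and 1 lower adjusted over the list alone, with Bmp2 at least 123-fold and Id3, Tgfb3 and Id1 at 8.37, 7.57 and 5.62. Cell cycle genes were higher in 17 of 24 (median 1.70, 0.959), 5 higher and 1 lower called by either adjustment, with Pcna at least 94.4-fold and Mcm4 at least 15.9-fold. Cartilage and bone genes were higher in 10 of 13 (4 and 7; 4.07, or 3.50 with bounds; 0.506), chondrocyte markers in 6 of 8 (2 and 4; 4.13; 0.609) and Hedgehog genes in 3 of 7 (1 higher and 1 lower; median -0.89, mean 0.43; 0.347). Macrophage markers were higher in 5 of 9 (2.97, or 0.80 with bounds; 0.878), T and NK cell in 2 of 6 (-1.17, 0.0817), B cell in 5 of 7 (1.70, or 1.20 with bounds; 0.752), endothelial in 8 of 11 (1.67, 0.506), Schwann cell in 4 of 8 (-1.04, 0.0825), skeletal muscle in 3 of 8 (-0.92, 0.0670) and satellite cell markers in 5 of 6 (2.77, or 1.35 with bounds; 0.726). For Hedgehog genes and macrophage and endothelial markers the test pointed lower.

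**Figure D2:**
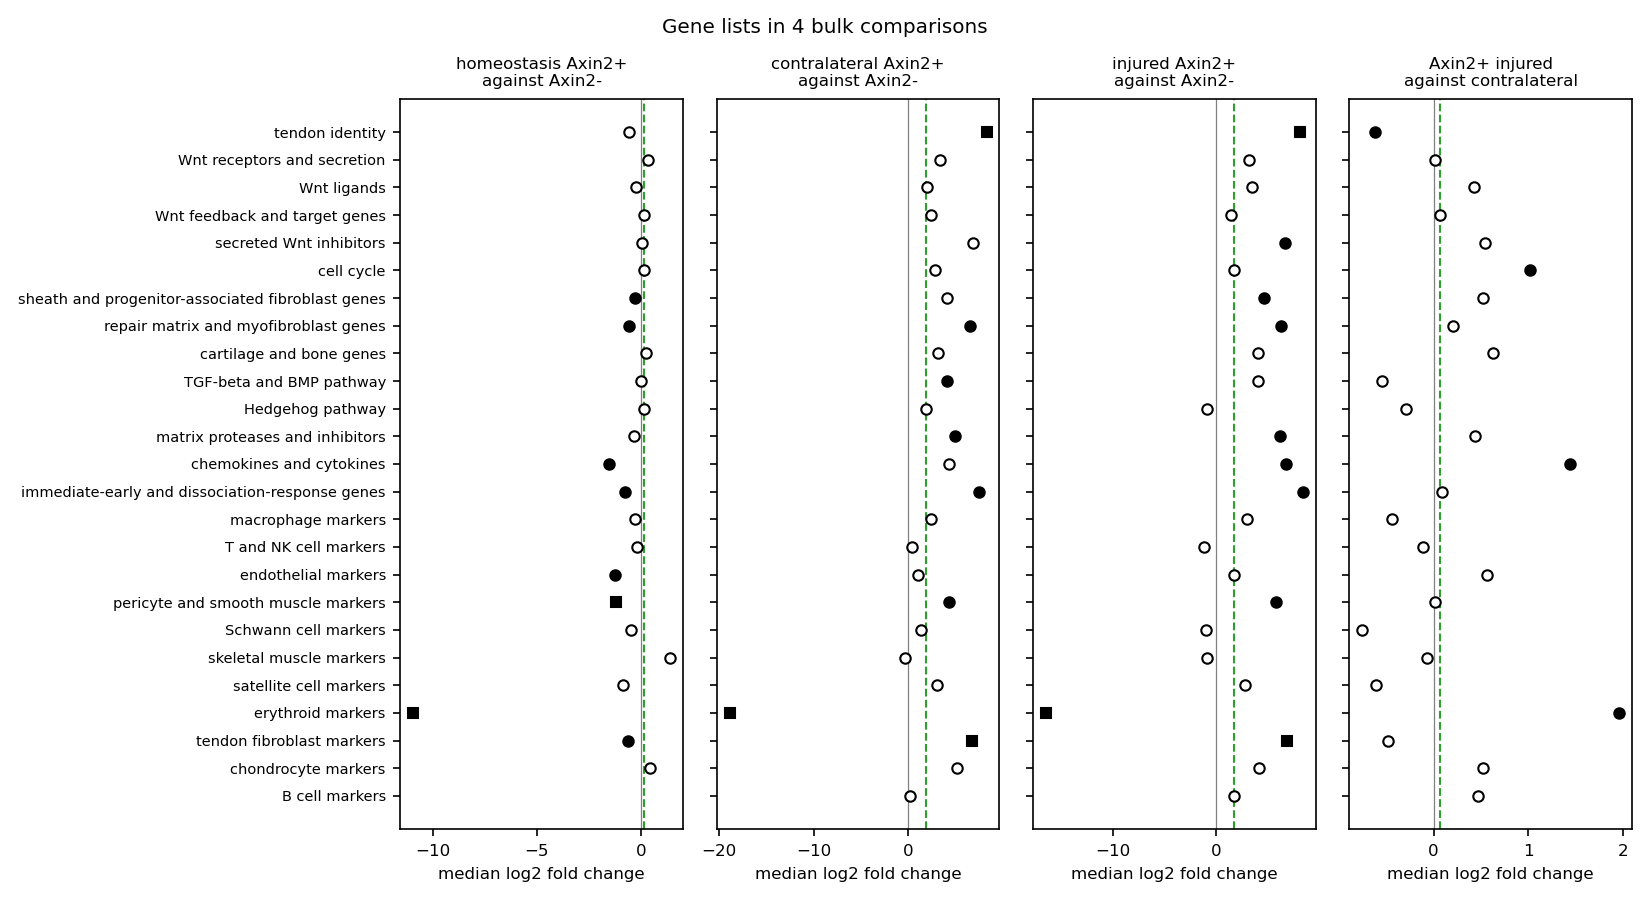
Median log2 fold change of each gene list in 4 bulk comparisons, with the median of all genes as a green dashed line; filled points were called by camera with its preset correlation, and squares also with an estimated correlation. Tendon identity had medians of 8.23 and 8.11 in the contralateral and injured comparisons of Axin2+ with Axin2-, where the median of all genes was 1.81 and 1.70.

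Between injured and contralateral Axin2+ libraries (n = 4 each), cell cycle and chemokine genes stood higher and tendon identity genes lower as lists, while no single gene passed the test. Cell cycle genes were higher in 22 of 24 (median 1.02 against 0.07 for all genes, camera adjusted p = 2.75e-07; adjusted p = 0.218 with an estimated correlation). Mki67 stood at 104 ± 75.8 against 12.7 ± 11.5 (log2 fold change 2.84, SE 1.45), and the mitotic genes Cdc20 and Aurkb had log2 fold changes of 3.72 and 2.97, none past the test. Chemokines were higher in 13 of 16 (median 1.44, camera adjusted p = 2.26e-05; adjusted p = 0.445 with an estimated correlation), a call that ended without C3 (0.0909) or C5 (0.10). Tendon identity genes were lower in 12 of 12 (median -0.61, camera adjusted p = 0.000893; adjusted p = 0.0769 with an estimated correlation). Tnmd stood at 5613 ± 3217 against 8064 ± 3526 (log2 fold change -0.67, SE 0.84), Scx at 1809 ± 3391 against 5708 ± 9288 (-2.46, SE 2.34) and Mkx at 899.8 ± 874 against 1538 ± 101 (-1.27). Erythroid markers were higher in 4 of 6 (median 1.96, camera adjusted p = 0.000378; adjusted p = 0.445 with an estimated correlation), a call that ended without B10 (0.0867). No member of these lists passed over all genes or adjusted over the list alone, and fry called 0 lists.

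The genes with the smallest p in Axin2+ cells after injury, none past the test (limma adjusted p = 1), were Kng2 (log2 fold change 4.28), Cyp1b1, a cytochrome P450 (chromosome 17, 79701537 to 79715061; 4.13, 259 ± 136 against 25.5 ± 28.6), the growth-cone protein Gap43 (3.85, 66.8 ± 26.3 against 4.08 ± 2.76), Gm10145 (at least 79.4-fold) and Cenpp (3.25) on the higher side. On the lower side they were Gm16042 (-3.52), Irs3 (-3.33), Cyb5r2 (-3.27) and Pcdhga11 (-2.83). Axin2 stood at 32.2 ± 41.4 against 12.1 ± 4.57 (log2 fold change 0.54, SE 1.49). limma called 0 genes and 140 had an unadjusted p under 0.05; edgeR called 0 (249), a fit to these 2 groups 0 (973) and array weights 2. Groups did not overlap for 607 genes (2.84%, against 2.86% by chance), and on simulated libraries the 4-group fit recovered 10.2% of genes changed 64-fold. Lists not called were Schwann cell markers (1 of 8 higher, camera adjusted p = 0.0641), TGF-beta and BMP (5 of 21, 0.0677), cartilage and bone (8 of 13, 0.0677), proteases (10 of 16, 0.125), tendon fibroblast markers (3 of 11, 0.149), Hedgehog (0.213), Wnt ligands (8 of 12, 0.230), repair matrix (11 of 18, 0.371) and B cell markers (0.371). Sheath genes (11 of 13) and chondrocyte markers had 0.488, Wnt inhibitors (5 of 8) 0.563, macrophage markers (3 of 9) 0.777, T and NK, endothelial and satellite cell markers 0.781, Wnt receptors (9 of 16), Wnt feedback genes (9 of 15) and skeletal muscle markers 0.858, and immediate-early genes (10 of 16) and pericyte markers (5 of 10) 0.913. For the last 5 of these, medians lay between -0.07 and 0.08 and median, mean and test did not all share a sign.

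Between injured (n = 2) and contralateral (n = 3) Axin2- libraries, in all of which globins took 49.7 to 62.7% of reads, the genes that rose most after injury included Ifit1, Tgtp2, Slfn14 and Usp18. Ifit1, an antiviral RNA-binding protein (chromosome 19, 34640871 to 34650009), stood at 5475 ± 1688 against 1.17 ± 2.03 (log2 fold change 11.66, SE 1.61, limma adjusted p = 0.00211). Tgtp2, an interferon-induced GTPase (chromosome 11, 49057194 to 49064206), was at least 2387-fold higher, Slfn14 at least 1608-fold and Usp18, a negative regulator of interferon signalling, at least 370.3-fold. Nacad, Ubl7 and Pspc1 had log2 fold changes of 11.04, 10.19 and 9.78. Lower were Btg2 (-8.67), Stau1 (-8.41) and Sbsn (-7.96), and, at 0 after injury, Mtfr1l (at least 72.9-fold), Nenf (65.3), Acat1 (50.4), Ptpn20 (48.6) and Vmn1r168 (48.3). Among list members, Lyz2, a myeloid lysozyme, the cyclin Ccna2 and Mmp2 had log2 fold changes of 9.02, 7.40 and 5.19, Acta2 was at least 237-fold higher and Sparc had -5.87. Every one of these calls ended with array weights and in a fit to the 2 groups alone. Axin2 (log2 fold change 0.05), Scx (0.11), Mkx (-0.30), Tnmd (3.07, limma adjusted p = 0.132) and Mki67 (2.80, 0.450) did not pass.

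limma called 890 genes in this Axin2- comparison, 526 higher and 364 lower (59.1% higher), and 4127 had an unadjusted p under 0.05. Groups did not overlap for 3401 genes (15.9%, against 20% by chance). edgeR called 663 (82.2% higher, 418 shared with limma), scaling without globins 418, pseudocount 5 529, a block of neighbouring wells 181, and array weights and the 2-group fit 0 each (745 at unadjusted p under 0.05 in the latter). Leaving out 1 library gave 526 (C7), 548 (C11), 565 (C9), 579 (B12), 1481 (C4), 1487 (C1; 43.0% higher), 2035 (C8) or 2802 (C6), and on simulated libraries limma called 831 unchanged genes. The calls on simulated libraries numbered 867 in all. No list was called (smallest camera adjusted p 0.436, for the cell cycle), and fry called B cell markers (adjusted p = 0.0374). With members at 0 at their bounds, medians moved from -1.41 to 0.14 for Wnt ligands, from -0.90 to 0.28 for chemokines, from -0.56 to 1.09 for pericyte markers and from -0.64 to -0.10 for tendon identity. Pericyte markers had a mean of 0.05, and the test for tendon fibroblast markers (median 0.23) pointed lower.

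By limma's test of the interaction, the injury response of Slfn14, Ifit1, Ubl7 and Nenf differed between Axin2+ and Axin2- libraries. These calls ended with edgeR, with array weights and with neighbouring wells as a block. The blocks were set by plate position: B10 to C1, C2 to C5, C6 to C9, and C11 alone. They need not match injured and contralateral tendons of the same animal, so pairing was not tested. Slfn14 differed by -11.68 on the log2 scale (SE 1.32, limma adjusted p = 0.00653), Ifit1 by -13.48 (SE 2.03, limma adjusted p = 0.0203) and Ubl7 by -10.37, each lower in the Axin2+ response, and Nenf by 8.86 (SE 1.19, limma adjusted p = 0.0142) the other way. As Slfn14 was at 0 in contralateral and Nenf at 0 in injured Axin2- libraries, their values rest on the pseudocount of 1 and are no bounds. The log2 fold changes of these genes within Axin2+ cells were -0.43, -1.82, -0.18 and 0.21. Tnmd differed by -3.74 (limma adjusted p = 0.271). limma called 79 genes, 24 higher and 55 lower (30.4% higher), and 2629 had an unadjusted p under 0.05. On simulated libraries of this design, 61 of its 71 calls were unchanged genes. edgeR called 0 (4384 at unadjusted p under 0.05), array weights 0 and a block of neighbouring wells 0; quantile normalization gave 42 (19.0% higher), scaling without globins 38 (13.2% higher) and pseudocount 0.1 506 (56.5% higher). Leaving out 1 library gave 1 (B12, C11, C7 or C9), 4 (C2), 7 (C3), 11 (B10), 22 (C5), 365 (B11), 391 (C4), 422 (C1; 61.8% higher), 748 (C8) or 1352 (C6) calls. No list was called by camera (smallest adjusted p 0.218), and fry called B cell markers (adjusted p = 0.0249). Median and mean differed in sign for Wnt inhibitors (-1.08 and 0.07), repair matrix (0.02 and -0.01), pericyte (0.25 and -0.02) and tendon fibroblast genes (0.06 and -0.41), and the protease test pointed lower at a median of 0.25.

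Fold changes of Axin2+ over Axin2- in homeostasis and in contralateral tendon, measured in separate tables, had a Pearson correlation of 0.0862 and a Spearman correlation of 0.0321 across 15158 genes, which are not independent replicates. The tables may hold different tendons, since for the homeostasis libraries the sample labels give Achilles tendon and the protocol gives tendons of the forelimb and hindlimb. Signs matched for 59.8% of genes. Of 6888 genes called in contralateral tendon, 4321 (62.7%) had the same sign in homeostasis, and of the 7 called in homeostasis, 6 had the same sign in contralateral tendon. Leaving out 1 library moved the correlation over all genes from 0.0051 (without A2) to 0.211 (without A8). Over genes called in either, it was 0.197.

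The single-cell libraries held 452 cells labelled homeostasis, 609 labelled 10 dpi and 1118 labelled as the 10 dpi Axin2 reporter-positive sort, with median depths of 5959.5, 4124 and 3776 UMIs. Tendon fibroblast-like cells, named by markers such as Tnmd and Fmod, made up 3.32% (95% exact binomial interval 1.87 to 5.41), 32.8% (29.1 to 36.7) and 3.58% (2.57 to 4.84). T and NK cell-like cells made up 1.11% (0.360 to 2.56), 0.164% and 55.0% (52.0 to 58.0), although the gate left out cells with surface CD45. Schwann cell-like cells made up 1.11%, 15.4% (12.7 to 18.6) and 0%, which allows up to 0.268%. Satellite cell-like cells, the muscle stem cells, made up 21.9% (18.2 to 26.0), 3.94% (2.54 to 5.81) and 0.179%, and skeletal muscle-like cells 3.98%, 0% (up to 0.4926%) and 0%. Macrophage-like cells made up 5.53% (3.61 to 8.06), 1.15% (0.463 to 2.35) and 8.77% (7.17 to 10.6), endothelial-like cells 6.86%, 9.85% and 2.15%, pericyte-like cells 6.42%, 9.03% and 2.06%, and neutrophil-like cells 4.42%, 0.4926% and 2.06%. Unnamed clusters made up 45.4%, 27.1% and 26.2%; the largest of them, led by Saa3, Cxcl5, Mmp3, Cthrc1 and Timp1, made up 27.4%, 2.96% and 25.1%. Clustering at a resolution of 1.0 put 23.9% of homeostasis and 19.7% of sorted cells in the tendon fibroblast-like class, and at most 20% mitochondrial UMIs gave 8.30% and 7.85%. With 1 library per group, all differences between these libraries lack a replicate check.

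**Figure D3:**
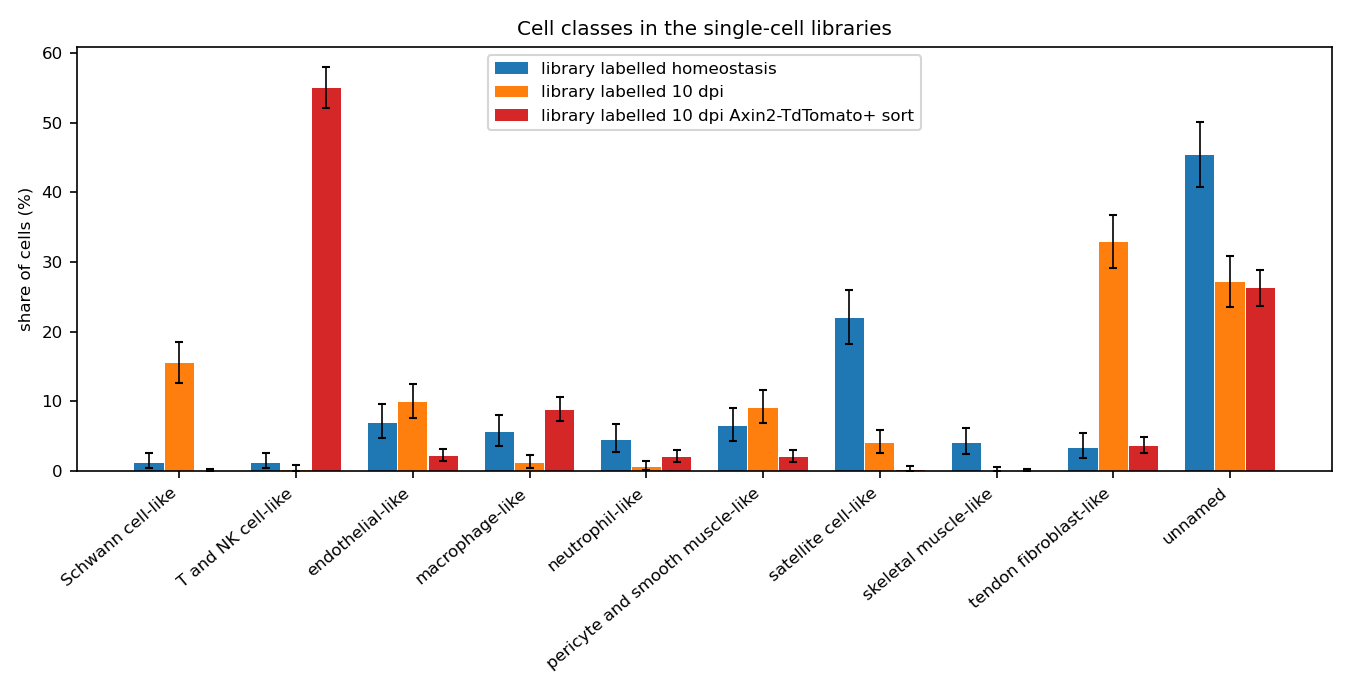
Share of cells (%) in each class in the 3 single-cell libraries, with bars for the share and whiskers for the exact 95% binomial interval. T and NK cell-like cells reach 55.0% in the sorted library, and tendon fibroblast-like cells 32.8% in the library labelled 10 dpi.

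Over all cells, Axin2 stood at 5.38 CPM (95% Poisson interval 3.63 to 7.68) in the homeostasis library, 22.6 (17.8 to 28.4) at 10 dpi and 11.7 (9.69 to 13.9) in the sort. The reporter transcript, Tdtomato, stood at 0.359 CPM, 28.4 CPM and 52.3 CPM. Within the sort it stood at 67.6 CPM (57.3 to 79.3) in T and NK cell-like cells, 61.1 (36.8 to 95.4) in tendon fibroblast-like, 127.7 (84.1 to 186) in endothelial-like and 8.06 (3.48 to 15.9) in macrophage-like cells. Axin2 in tendon fibroblast-like cells stood at 29.6 CPM (9.61 to 69.1, 5 UMIs), 25.7 CPM (17.9 to 35.7, 35 UMIs) and 19.3 CPM (7.08 to 42.0, 6 UMIs) in the 3 libraries, intervals that overlap; in homeostasis it was 8.34 CPM at a resolution of 1.0, 5.49 CPM over all collagen-rich clusters and 5.38 CPM over all cells.

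Tendon fibroblast-like cells of the library labelled 10 dpi (200 cells), set against those of the library labelled homeostasis (15 cells), held fewer cell cycle transcripts and more of several tendon matrix genes. All 12 cell cycle genes were lower (median log2 ratio -6.23, percentile 0 of random lists), and Mki67 went from 30 UMIs to 0, at least 80.7-fold lower. A few cycling cells among the 15 could give these values, so they need not describe the class as a whole. Tendon identity genes were higher in 9 of 12 (median 1.07, percentile 100), with Chad at 7.29 times (5.91 to 9.09) and Comp at 4.20 times, but Scx stood at 806 against 1977 CPM (ratio 0.408, 0.360 to 0.462) and Tnmd at 3071 against 4522 CPM (0.679, 0.629 to 0.735). Over all collagen-rich clusters these ratios turned to 1.35 for Scx and 3.08 for Tnmd, and at a resolution of 1.0 both were also above 1. Mkx had a ratio of 1.97 (1.04 to 4.19). Sheath genes were higher in 10 of 11 (1.31, percentile 100), with the lubricant Prg4 at 9.13 times (7.83 to 10.7), and Wnt inhibitors in 4 of 4 (2.12, percentile 100), with Wif1 at 11.3 times (5.15 to 30.9); the sheath median was -0.40 from 500 UMIs and -0.52 with up to 20% mitochondrial UMIs, and that of Wnt inhibitors -0.22 at a resolution of 1.0 and -0.10 over collagen-rich clusters (3 of 7 higher, percentile 40.5). Klk1, a kallikrein protease, was at least 148-fold higher and Myoc 73.9 times (38.9 to 162), and Adamts2, with 1 UMI in homeostasis, 92.3 times (16.5 to 3649.8). The collagenase Mmp13 was lowest, with 1 UMI against 131. Chemokines were lower in 5 of 7 (-1.05, percentile 0.200; 0.13 from 2000 UMIs), with Ccl2 at 0.0955 times, and Wnt ligands in 3 of 4 (-1.06, percentile 0.920). Postn had a ratio of 0.338 and Cthrc1 0.224. Scx, Tnmd and Comp are among the markers that name this class, so their levels within it are not independent of the naming. Klk1, Myoc, Prg4 and Chad also lead cluster 16, whose 51 cells all came from the 10 dpi library, while cluster 10 held the other 15, 149 and 40 cells of this class.

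Cartilage and bone genes were higher in 4 of 4 (median log2 ratio 1.02, percentile 99.9) in the same comparison. Repair matrix genes were higher in 6 of 16 (-0.29, percentile 12.99), TGF-beta and BMP genes in 9 of 17 (0.03, 84.1), immediate-early genes in 4 of 16 (-0.22, 22.8), proteases in 5 of 12 (-0.13, 43.9), Wnt feedback genes in 1 of 6 (-0.45, 9.97) and Wnt receptors in 1 of 9 (-0.39, 16.7). The median of all genes was -0.07. A simulated list with no change, beside raised genes that took share from it, had -0.29 (percentile 8.15). Cartilage and bone genes had a median of -0.32 at a resolution of 1.0. Over all collagen-rich clusters the medians of Wnt feedback genes (0.82), Wnt ligands (0.70) and immediate-early genes (0.63) were above 0. There, repair matrix genes were lower in 17 of 18 (-1.66, percentile 0), cell cycle genes in 23 of 24 (-3.21, percentile 0), and tendon identity genes higher in 11 of 12 (1.96, percentile 100).

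In the 10 dpi reporter-positive sort, tendon fibroblast-like cells (40 cells) held more repair matrix transcripts than those of the unsorted library labelled 10 dpi (200 cells). Repair matrix genes were higher in 13 of 17 (median log2 ratio 1.44, percentile 100), with Cthrc1, a secreted protein of injured matrix, at 10.2 times (8.73 to 11.98), Acta2 7.48 times (6.46 to 8.69), Col3a1 4.44 times (4.14 to 4.77) and Postn 4.32 times (3.92 to 4.75). Scx stood at 1443 against 806 CPM (1.79 times, 1.60 to 2.001) and Tnmd at 2.51 times (2.39 to 2.64), but over all collagen-rich clusters the ratios were 0.630 and 0.753, and at a resolution of 1.0 both were also below 1. In this class tendon identity genes as a list were lower in 10 of 12 (-0.87, percentile 0.0200; 0.28 with up to 20% mitochondrial UMIs and 0.07 with doublets kept), with Kera, Chad and Comp at ratios of 0.219, 0.275 and 0.348. Crabp2, a retinoic acid carrier, stood at 12.1 times, Mmp13 at 202 times (34.4 to 8136; 46 UMIs against 1) and Wnt16 at 67.9 times (17.3 to 586; 31 UMIs against 2). Wnt inhibitors were lower in 3 of 4 (-2.60, percentile 0), with Sfrp2 at 0.0985 and Wif1 at 0.128. Klk1, at 0 UMIs in the sort, was at least 273-fold lower, Myoc had a ratio of 0.0196 (0.0125 to 0.0292) and Prg4 0.0919. Axin2 (0.752, 0.258 to 1.81), Mkx (0.882, 0.584 to 1.30) and Tdtomato (1.32, 0.747 to 2.24) had intervals that include 1, and Mki67 had 0 UMIs in both. Immediate-early (3 of 16 higher, -0.46, percentile 0.0400), chemokine (2 of 7, -0.79, 0.270), sheath (2 of 11, -0.50, 1.52), protease (6 of 12, -0.36, 1.39), TGF-beta and BMP (7 of 17, -0.24, 3.01) and cartilage genes (1 of 5, -0.65, 4.03) had low percentiles, although the means of the protease (0.03) and cartilage lists (0.19) were above 0. Wnt ligands (5 of 5 higher, 0.13, 90.0), Wnt receptors (0.11, 69.99) and Wnt feedback genes (-0.14, mean 0.19, 56.6) lay nearer the middle. Cell cycle genes were lower in 4 of 4 (-0.84, percentile 4.15) in this class but higher in 23 of 25 over all collagen-rich clusters (3.36). There, chemokines were also higher, in 11 of 17 (0.66, percentile 99.9), proteases in 10 of 17 (0.39, 96.1) and cartilage genes in 4 of 7 (0.29, 87.5), while Wnt feedback genes were lower in 10 of 11 (-1.15, percentile 0.0800) and Wnt receptors had a median of -0.12. Wnt ligands had a median of -0.87 with up to 20% mitochondrial UMIs and -1.10 with doublets kept.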

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

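Of the tests below, those of red blood cell RNA, of dissociation stress and of a higher share of tendon cells were chosen only after the result was seen, as were thinning, scaling without globins and the comparison of plate sections (wells A1 to A4 with A5 to A8, B10 to C4 with C5 to C11).

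Most called genes stood lower in the globin-rich Axin2- libraries of the contralateral and injured limbs. A lower number of non-globin reads alone is argued against in the contralateral limb. With Axin2+ libraries thinned to 6727999 non-globin reads, the median of the Axin2- libraries, 83.69% of 7628 called genes were still higher in Axin2+. Thinning matches read numbers only. At 6576381 non-globin reads, Axin2+ replicate C11 held 18185 genes with at least 10 reads. The contralateral Axin2- libraries, at 6655386 to 7845458, held 6057 to 11324. Whether fewer distinct transcripts were captured in the Axin2- wells was not tested. The scaling stays open. With globins left out, which moves all genes of a library alike, 94.82% of 10031 were higher. With edgeR 64.5% were (76.6% in the injured limb), but it changed test and scaling at once, so the drop cannot be put down to scaling. Quantile normalization gave 49.4% (50.8% in the injured limb). It makes all libraries' distributions equal, so an even share was fixed in advance and tests nothing. Red blood cell RNA in the Axin2- wells is a candidate explanation: 19 red cell transcripts other than globins had a median log2 fold change of Axin2- over Axin2+ of 9.02 in the contralateral limb and 8.43 in the injured limb, against 0.27 for 13 such transcripts in homeostasis, and the bulk gate does not list TER-119, the red cell marker, which the single-cell gate excluded. All 5 Axin2- libraries of that experiment carry the signal, so no count without them can be given, and a difference between Axin2+ and Axin2- tendon cells stays open beside it.

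Scx in the homeostasis libraries followed the plate section and not the reporter: 52.5 to 87.8 scaled reads at A1 to A4 and 1076 to 6591 at A5 to A8 (log2 difference 4.95). More tendon cells at A5 to A8 are argued against, since the other 11 tendon identity genes had a median log2 difference of -0.43, each below 2. Reads of Bop1, the gene whose intron holds Scx, cannot be told apart from this pattern, because Bop1 differed in the same direction by 1.19. Xist, the X inactivation RNA, differed by plate section too, at 8.21 to 19.1 against 509 to 1708, while in the Axin2+ libraries of the injury experiment, with Scx at 2.72 to 166 at B10 to C4 and 172 to 19476 at C5 to C11, Xist overlapped (13.5 to 44.5 and 17.2 to 80.9). The labels give no group for the plate sections and tie no wells to animals. A difference between animals, such as sex, cannot be told apart from the plate section and was not tested.

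The single-cell library labelled homeostasis held fibroblasts rich in cell cycle and repair matrix transcripts, and that labelled 10 dpi held fibroblasts rich in tendon identity transcripts. Stress of dissociation stays open, with 1 library each. Immediate-early and dissociation-response genes had a median log2 ratio of homeostasis over 10 dpi of -0.63 in collagen-rich clusters (5 of 16 higher). In tendon fibroblast-like cells it was 0.22 (12 of 16 higher), where the reverse ratio lay at percentile 22.8 of random lists. An exchange of the labels between the unsorted libraries stays open: across 10573 genes, the ratio of 10 dpi over homeostasis in collagen-rich clusters had a Pearson correlation of -0.372 with the bulk fold change of Axin2+ injured over contralateral, but 7 of the 70 ways to label the bulk libraries gave a value as low, and Tdtomato, at 0.359 CPM in the homeostasis library, 28.4 CPM at 10 dpi and 52.3 CPM in the sort, runs with the labels as given, which do not say which mice carried the reporter. With exchanged labels, the ratios of the sort over 10 dpi would set sorted cells against homeostasis cells. A true difference between the libraries, with 1 library each, stays open and untested.

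In 10 of 224 groups of 4 libraries, 1 library stood apart from the rest, where chance gives about 1 in 20 groups; the value is the gap to the nearest library as a share of the group's range. Among contralateral Axin2+ libraries, the Wnt receptor Fzd7 (0.853) and the matrilin Matn3 (0.836) were lowest in C3, Plpp1 (0.904) highest in C3, and Myc (0.912) and Has1 (0.8291) highest in C7. Fam102a was lowest in homeostasis Axin2- replicate A4 (0.839). Among injured Axin2+ libraries, Gm16042 (1) was highest in B10 and Tgfb3 (0.928) highest in C9. The globin share was highest in contralateral Axin2+ replicate C11 (0.894) and homeostasis Axin2+ replicate A1 (0.977).

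For 16 named genes the injury response differed between Axin2+ and Axin2- libraries by limma's test of the interaction, and 15 are given here. The log2 response of Axin2+ minus that of Axin2- was above 0 for Mtfr1l (8.93), Nenf (8.86), Mlf1 (7.95), Msl1 (7.88), Acat1 (7.76), Fndc3a (7.60), Ptpn20 (7.47) and Olfr822 (7.43). It was below 0 for Ifit1 (-13.48), Slfn14 (-11.68), Usp18 (-10.83), Ubl7 (-10.37), Nacad (-10.33), Pspc1 (-9.78) and Rbm14 (-9.38). All 8 above 0 were at 0 in injured, and Slfn14 and Usp18 in contralateral Axin2- libraries, so these values rest on the pseudocount of 1 and are no bounds. Each of these calls ended with edgeR and with array weights.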

How the results depend on the processing

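Chosen after seeing the data were edgeR, the plate section term, scaling without globins, each plate section alone, the minimum of 1, the block of neighbouring wells in the injury experiment, thinning, and the single-cell sets without T and NK cells, of collagen-rich clusters or of all cells; the others were planned. No call of a named bulk gene or a list changed direction; the share of interaction calls that were higher went from 30.4% to 56.5% with pseudocount 0.1 and 61.8% without C1, that of Axin2- injury calls from 59.1% to 43.0% without C1, and the contralateral median of all genes from 1.81 to -0.20 with quantile normalization. Over collagen-rich clusters, 10 dpi over homeostasis, Scx went from 0.408 to 1.35, Tnmd from 0.679 to 3.08 and the median of Wnt feedback genes from -0.45 to 0.82, and for the sort over 10 dpi that of cell cycle genes from -0.84 to 3.36. Under at least 1 alternative the median changed sign for 10 of 13 lists of 10 dpi over homeostasis and 7 of 13 of the sort over 10 dpi; the cause was not tested. Of bulk counts and lists, 111 stayed within 1.5 times or on their side of the threshold, 50 moved, 11 lost and 3 gained a call; of values of named bulk genes, 5672 kept their side, 564 lost and 4 gained it, and of single-cell values of named genes and classes 238 stayed within their interval and 172 moved. Calls held under every alternative for 59 of 85 named genes in the contralateral, 57 of 84 in the injured, 0 of 6 in the homeostasis and 0 of 21 in the Axin2- injury comparison, and for 0 of 16 in the interaction; apart from fewer genes or libraries, the cause was not tested.

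Homeostasis calls were 2 with pseudocount 0.1, 4 with edgeR, 3 without globins, 34 at A1 to A4 and 0 at A5 to A8 (462 at unadjusted p under 0.05). Array weights gave 4946 contralateral, 2736 injured, 2 Axin2+ injury, 0 Axin2- injury and 0 interaction calls, and edgeR 3264 injured and 0 interaction calls (4384 at unadjusted p under 0.05). Axin2- injury calls were 529 with pseudocount 5, 0 with only those 2 groups (745 at unadjusted p under 0.05), 418 without globins and 181 with the block. Interaction calls were 506 and 41 with pseudocounts 0.1 and 5, 42 with quantile normalization, 46 with the plate section, 38 without globins, 50 with the minimum of 1 and 0 with the block. With 1 library left out, limma called 0 to 17 genes in homeostasis, 6035 to 8920 in contralateral, 4357 to 7199 in injured tendon, 0 to 0 in Axin2+ injury, 526 to 2802 in Axin2- injury and 1 to 1352 in the interaction, and the correlation of homeostasis with contralateral fold changes ran from 0.0051 to 0.211 (0.197 over genes called in either). Without B11 or C6 the lone injured Axin2- library is assumed to vary like the other groups. Lists called with an estimated correlation and by fry were 2 and 2 in homeostasis, 3 and 20 in contralateral, 3 and 19 in injured tendon, 0 and 0 in Axin2+ injury, and by fry 1 in Axin2- injury and 1 in the interaction. Nothing in the labels pairs wells, and no fit paired injured with contralateral tendons by animal. With neighbouring wells as a block limma called 10 genes in homeostasis (1218 at unadjusted p under 0.05, against 577 without the block).

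Tendon fibroblast-like shares in the homeostasis, 10 dpi and sorted libraries were 5.76%, 37.4% and 8.31% from 500 UMIs, and 8.30%, 41.5% and 7.85% with up to 20% mitochondrial UMIs. They were 39.0% at 10 dpi from 2000 UMIs, 23.9% in homeostasis and 19.7% in the sort at resolution 1.0, and in the sort 8.57% with doublets kept and 7.95% without T and NK cells. Axin2 in that class in homeostasis was 8.34 CPM at resolution 1.0, 5.49 over collagen-rich clusters and 5.38 over all cells, against 29.6 from 5 UMIs. The TPM table planned for homeostasis was not run, since it holds other libraries.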

Other observations

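The tests of other splits of the libraries were planned, and the values over all cells were chosen after seeing the data. Over all cells, Schwann cell markers were higher in the single-cell library labelled 10 dpi than in that labelled homeostasis in 8 of 8 (median log2 ratio 3.36), erythroid markers in 5 of 5 (2.25), B cell markers in 3 of 3 (1.26), chondrocyte markers in 4 of 5 (0.69) and tendon fibroblast markers in 8 of 11 (1.02). Macrophage markers were lower in 14 of 14 (-2.43), skeletal muscle markers in 9 of 9 (-6.30), T and NK cell markers in 4 of 4 (-2.17), satellite cell markers in 5 of 6 (-1.08) and neutrophil markers in 4 of 5 (-0.82). Endothelial (0.03) and pericyte markers (0.11) lay near 0. Hedgehog genes were higher in 5 of 6 (1.15).

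Compared with the unsorted library labelled 10 dpi, the sorted library held more T and NK cell markers (7 of 7, median log2 ratio 6.37), macrophage markers (14 of 14, 3.50) and keratinocyte markers (3 of 4, 3.44), and fewer erythroid (5 of 5, -11.44), Schwann cell (8 of 8, -4.23), satellite cell (5 of 5, -3.85), pericyte (10 of 10, -2.12) and endothelial markers (11 of 11, -1.76). Hedgehog genes were lower in 6 of 6 (-2.09). Cells held 47.5% of all UMIs in the library labelled 10 dpi and 87.4% in the sort, so background RNA may differ between them. Ptprc, the gene of CD45, stood at 15.6 CPM in the homeostasis library, 7.64 CPM at 10 dpi and 85.2 CPM in the sort, and Cre recombinase transcripts had 0, 2 and 3 UMIs. Tdtomato had 0 UMIs in the 94 Schwann cell-like cells at 10 dpi.

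Of the 35 splits of the homeostasis libraries into 4 and 4, 2 called at least the real 7 genes, so chance is not excluded. The other one, A1 to A4 against A5 to A8, called 823. Xist also differed by that split, so plate section, animal and sex cannot be told apart. Every remaining split called at most 2. With a term for the plate section limma called 8 genes, within A1 to A4 34 and within A5 to A8 0 (462 at unadjusted p under 0.05). For the 8 lists called there, 8 of 35 splits gave as many (highest other 10), and chance is not excluded. For the 7760 genes of the contralateral comparison only the real split of 35 gave as many (highest other 7). That share, 0.0286, is under the preset 0.05 but is the smallest that 35 splits can give. The real split also parts the globin-rich Axin2- libraries from the others, so it does not say what differs. For the 8 lists of that comparison, 9 of 35 splits gave at least as many (highest other 12). For Axin2+ injury, with 0 genes called, 35 of 35 splits give as many whatever the data (highest other 4), so the count tests nothing, and 22 of 35 gave at least the real 4 lists (highest other 9). For the correlation of 0.0862 between homeostasis and contralateral fold changes, 19 of 35 splits gave one as large (highest other 0.237). Chance is not excluded for these lists and this correlation.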
